A study of Homo sapiens with 9 samples.

How the data were processed

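Bulk RNA sequencing was done on 9 libraries of MCF7 cells, in 3 groups of 3 that the labels call NC with DMSO, SETDB1 with DMSO and SETDB1 with LMB. Per the labels, the genotype of the NC cultures is wild type and that of the others is SETDB1 overexpression. RNA was extracted from triplicate cultures with TRIzol and a column kit, and libraries were made with a BGI kit for mRNA, per the labels' protocols. The submitters' processing notes list HISAT2 2.2.1 and the genome build hg38. The read counter, the annotation, the filters and whether strand was used are not given in the sources used here. The length, dose and timing of the LMB treatment are not given there either.

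The deposited table holds FPKM values (fragments per kilobase of gene, scaled to the number of mapped fragments), calculated by the authors and rounded to 2 decimals, per the file headers. It has 1 column per library and 17600 genes under Entrez identifiers. Symbols and positions came from an NCBI gene table for assembly GRCh38.p14, the same build as hg38, and 17558 identifiers matched. FPKM values are not counts, so no count model was fitted. The columns were used as deposited, and their sums differed between libraries. Because FPKM divides by all mapped fragments, a few abundant transcripts that take a larger share lower the values of the rest, so 3 rescalings were among the alternatives. Values near 0 move in steps of 1 read. The ratio of these steps to the NC libraries, read from 536 low genes, gave each library's relative depth. Total read numbers are unknown, so no counting interval was given. Genes with near-identical copies, such as MTRNR2L, histone, tubulin and ribosomal protein genes, can share reads, and their values are uncertain for that reason. Overlapping and antisense genes carry the same uncertainty.

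Values were analysed as log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 9 libraries were kept, which left 11505. All 9 libraries entered 1 fit with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with the group as the only factor. Comparisons were SETDB1 against NC in DMSO, LMB against DMSO in SETDB1 cells, and SETDB1 with LMB against NC with DMSO. A gene was called higher or lower when the Benjamini-Hochberg adjusted p over all genes kept was under 0.05. A log2 fold change is the difference of group means on the log2(FPKM + 1) scale, and this scale understates the change of low genes. The SE and the adjusted p come from the same fit. FPKM values are given as mean ± SD of 3 libraries. With 3 libraries against 3, 10% of genes are fully separated by chance.

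Gene lists were fixed before the data were examined: glycolysis and lactate, MYC targets, oxidative phosphorylation (nuclear genes), mitochondrially encoded mRNAs, tricarboxylic acid cycle, hypoxia response, epithelial junction, mesenchymal and invasion, estrogen receptor targets, luminal identity, p53 targets, cell cycle S phase, cell cycle mitosis, nuclear transport, H3K9 and DNA methylation machinery, interferon response, NF-kappaB and inflammatory genes, integrated stress response, endoplasmic reticulum chaperones, heat shock response, cholesterol synthesis, fatty acid synthesis, lysosome, NRF2 targets, immediate early genes, cytosolic ribosomal proteins, numbered zinc finger genes, clustered protocadherins, replication-dependent histones, and markers of basal or mesenchymal breast lines, fibroblasts, blood and endothelium. The list of mitochondrially encoded mRNAs had 0 members in the table. The other 32 lists were tested against the remaining genes with limma's camera at a preset correlation of 0.01, adjusted over all lists and all 3 comparisons. An estimated correlation, with which camera also uses only the residual degrees of freedom of the fit, and fry were the alternatives. Counts of members are from the fit over all genes, and a second count was adjusted over the list alone.

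Genes were named by a rule also fixed before the data were examined. It took SETDB1, MYC, LDHA and XPO1 in every comparison. It took the 8 largest rises and the 8 largest falls per comparison among called genes whose groups did not overlap, and up to 4 called members per list with the smallest p. Where no member was called, up to 2 were given as values, and a gene named in 1 comparison could be given in the others. The fit was tested on simulated data with 50 genes changed per size. In SETDB1 against NC it called 32% of genes changed by 0.26 on the log2 scale, 94% at 0.58, 100% at 1 and 100% at 2, with 10 false calls among 11505 genes. Far fewer genes were changed there than the 3118 called in the data, which makes the adjusted p stricter. The shares for small changes therefore need not hold for the data.

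Alternatives set before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, rescaling to TPM, median-of-ratios scaling, quantile normalization, eBayes without a trend, robust eBayes, only the libraries of the groups compared, the replicate number as a block, a minimum absolute log2 fold change of 1, and leaving out each library. After the data were seen, 2 more were added. One removed the MTRNR2L genes and rescaled each library. The other subtracted from each gene in the SETDB1 libraries the median change against NC of its 40 nearest tested genes on the chromosome. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.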

Results

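MCF7, an established breast cancer cell line that carries the estrogen receptor, was profiled by RNA sequencing in 9 libraries, in 3 groups of 3. The first group was the control line NC treated with the solvent DMSO. The second overexpressed SETDB1, a methyltransferase for histone H3 that is best known for silencing genes and retroelements in the nucleus, and received DMSO. The third overexpressed SETDB1 and received LMB, read here as leptomycin B, which blocks the nuclear export receptor XPO1. The series title concerns SETDB1 in the cytoplasm, the Warburg effect through c-MYC and LDHA, and migration and invasion. No NC culture with LMB was analysed here, so the response to LMB was measured only in SETDB1 cells. The labels name triplicate cultures without saying how each was started, so p-values measure the spread between these libraries.

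The FPKM values of 17600 genes summed to between 468852 and 486785 per library. Relative to NC, the estimated depth of the libraries was 0.71 for SETDB1 DMSO replicate 1, 1 for SETDB1 DMSO replicates 2 and 3, and 0.88, 0.88 and 0.9 for the LMB libraries. These estimates rest on the most frequent ratio of low values. For SETDB1 DMSO replicate 1, 34 of 270 ratios lay within 0.08 of it on the log2 scale. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.995 to 0.998 within groups and 0.912 to 0.99 between groups. The first principal component held 88.4% of the variance and set the 3 LMB libraries apart from the other 6. The second held 6.8% and set NC DMSO apart from SETDB1 DMSO. MTRNR2L genes, nuclear copies of a mitochondrial ribosomal RNA sequence, held 2.73% ± 0.05 (SD, n = 3) of summed FPKM in NC, 2.82% ± 0.105 in SETDB1 DMSO and 7.25% ± 0.31 in LMB. The median FPKM over all genes was 4.46 ± 0.022, 4.47 ± 0.055 and 3.88 ± 0.028 in the same order.

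**Figure D1:**
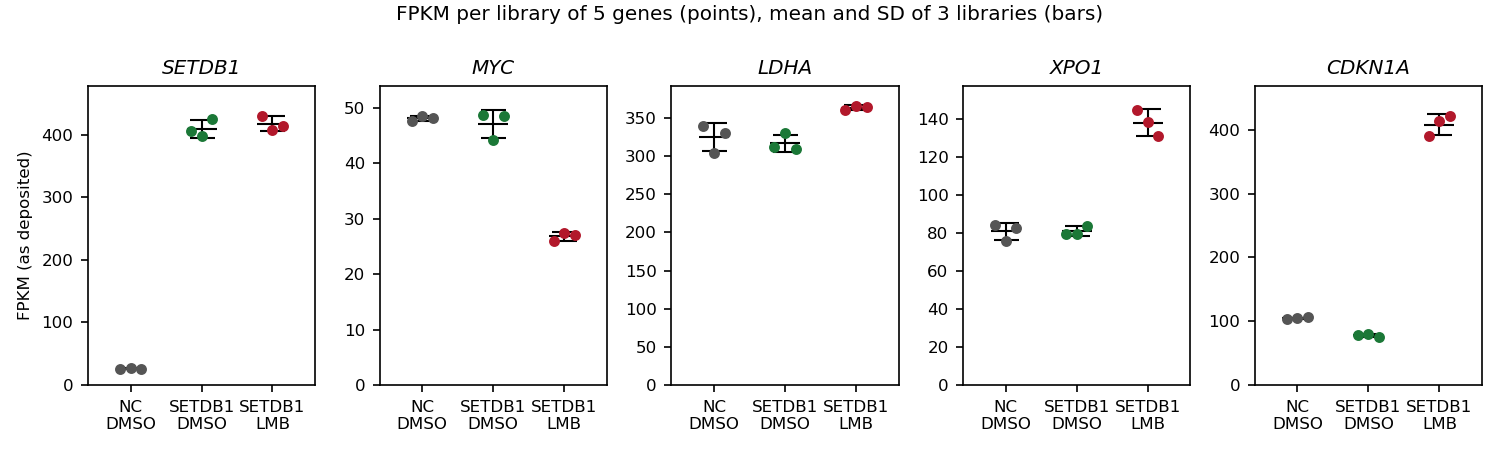
FPKM of SETDB1, MYC, LDHA, XPO1 and CDKN1A in each library (points, linear axes from 0) for NC DMSO, SETDB1 DMSO and SETDB1 LMB, with the mean and SD of 3 libraries as bars. SETDB1 was near 25.9 in NC and above 397 in all 6 SETDB1 libraries, MYC was lower only with LMB, and XPO1 and CDKN1A were higher with LMB.

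The first comparison asked what overexpression of SETDB1 changed in DMSO-treated cells. SETDB1 (Entrez 9869, chromosome 1, 150926263 to 150964737) stood at 25.9 ± 0.945 FPKM (SD, n = 3) in NC and 409.6 ± 14.7 in SETDB1 cells, a log2 fold change of 3.94 (SE 0.0454, adjusted p = 1.51e-15). Genes induced by interferon fell together, calprotectin and the integrin subunit ITGB6 fell, and SHH, CA2 and MUC1 rose. MYC (Entrez 4609, chromosome 8, 127735434 to 127742951), a transcription factor that drives growth genes, was at 48.1 ± 0.475 and 47.1 ± 2.56, with a log2 fold change of -0.03 (SE 0.0485, adjusted p = 0.694). LDHA (Entrez 3939, chromosome 11, 18394563 to 18408425), which reduces pyruvate to lactate, was at 324 ± 18.4 and 317 ± 11.2, with a log2 fold change of -0.03 (SE 0.0482, adjusted p = 0.667). For neither of these genes was the difference larger than the spread between replicates. These are RNA levels, and the data do not cover protein level, protein activity or lactate.

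Among the largest rises, SHH, a secreted hedgehog ligand, went from 5.4 ± 0.786 to 76.3 ± 3.97 FPKM (log2 fold change 3.60, SE 0.076). CA2, a carbonic anhydrase, went from 72.1 ± 2.91 to 300.5 ± 2.92 (2.05), and MUC1, a cell surface mucin, from 54.4 ± 11.3 to 189 ± 10.2 (1.80). DHRS2, a short-chain dehydrogenase, rose by 1.79 on the log2 scale, as did FGD3, an exchange factor for CDC42. KLK11, a secreted serine protease, rose by 1.74, and CITED4, a transcriptional coactivator, rose to 43.1 ± 2.04 FPKM. Among the largest falls, S100A8 and S100A9, the subunits of calprotectin, had log2 fold changes of -2.54 and -1.997, and S100A7 (psoriasin) fell by 2.08. AREG, a ligand of the EGF receptor, went from 109.5 ± 4.99 to 29.4 ± 0.996 FPKM (-1.86). PLS3, an actin-bundling protein, fell by 1.78, and KRT81, a hair keratin, fell by 1.52.

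Of 31 interferon response genes tested, 29 fell and 0 rose, and the same counts were obtained adjusted over the list alone. The median log2 fold change was -0.62, and the camera adjusted p was 8.61e-25, or 0.00174 with an estimated correlation. MX1, an antiviral GTPase, went from 10.7 ± 0.577 to 2.35 ± 0.247 FPKM (-1.80, adjusted p = 4.46e-09). IFIT1, an RNA-binding antiviral protein, fell by 1.42. IFI6, the most abundant of the list in NC, went from 419 ± 24.5 to 174 ± 12.1 (-1.26). PARP9, a partner of STAT1, fell by 0.85.

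Of 24 glycolysis and lactate genes, 9 rose, 1 fell and 14 did not pass the test. Adjusted over the list alone, 14 rose and 2 fell. The median was 0.15, and the list was called higher with an adjusted p of 0.00272, but the adjusted p was 0.156 with an estimated correlation. HK2, which phosphorylates glucose, went from 7.35 ± 0.17 to 12.5 ± 0.339 FPKM (0.69, adjusted p = 9.7e-07), and ENO2, an enolase, rose by 0.66. PFKFB3, which makes the activator of phosphofructokinase, fell by 0.42. ALDOA, an aldolase, went from 1263 ± 104 to 1827 ± 67 (0.54, adjusted p = 3.73e-05). ALDOA lies on chromosome 16 at 30064279 to 30070420, where neighbouring genes moved with it, and its adjusted p was 0.278 with the change of its neighbours subtracted (2.27e-06 to 0.278 over all alternatives).

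Of 50 MYC targets, 5 rose and 14 fell, also adjusted over the list alone, with a median of -0.09. The list was called lower with an adjusted p of 0.0115 (adjusted p = 0.332 with an estimated correlation). BYSL, a factor in assembly of the small ribosomal subunit, fell by 0.29, and PRMT3, an arginine methyltransferase of a ribosomal protein, fell by 0.38. Cytosolic ribosomal protein genes had 22 of 84 lower and 0 higher, also adjusted over the list alone (adjusted p = 1.5e-05, and 0.521 with an estimated correlation). Their call was also lost with quantile normalization (0.0878) and with fry (0.0554), over a range of 1.32e-08 to 0.521. RPS13 fell by 0.31 and RPL27A fell by 0.25.

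Mesenchymal and invasion genes were lower as a list, with 2 of 20 higher and 10 lower (adjusted over the list alone, 3 and 11), a median of -0.20 and an adjusted p of 0.00043 (adjusted p = 0.0568 with an estimated correlation). ITGB6, an epithelial integrin subunit that activates TGF-beta, went from 14.4 ± 0.746 to 3.22 ± 0.0265 FPKM (-1.87). FN1 (fibronectin) fell by 0.74 and TGFB2, a TGF-beta ligand, fell by 0.75, while CD44, a hyaluronan receptor, rose by 0.68. Markers of basal or mesenchymal breast lines had 1 of 8 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.011, and 0.107 with an estimated correlation). In that list ANXA1 (-1.14), CAV1 (-0.42) and FOXC1 (-0.54) fell. Of 17 luminal identity genes, 9 rose and 0 fell, also adjusted over the list alone, with a median of 0.17 (adjusted p = 0.00039, and 0.156 with an estimated correlation). Besides MUC1, XBP1, a transcription factor of secretory cells, rose by 0.34, TBX3 rose by 0.47, and AR, the androgen receptor, rose by 0.43.

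Estrogen receptor targets were not called as a list, with 11 of 30 higher and 7 lower, also adjusted over the list alone, a median of 0.03, a mean of -0.01 and the test direction up (adjusted p = 0.358). AREG fell, as did EGR3, an early growth response factor (-1.09), while IGFBP4 rose by 0.55 and AGR2, a disulfide isomerase, rose by 0.54. Mitosis genes had 9 of 32 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0357, and 0.492 with an estimated correlation). That call was lost without NC replicate 2 (0.224), without SETDB1 DMSO replicate 3 (0.0998) and with quantile normalization (0.0715), over a range of 0.00267 to 0.492. PLK1, a mitotic kinase, rose by 0.57. NF-kappaB and inflammatory genes had 4 of 8 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0171, 0.217 with an estimated correlation, and 0.113 with no filter on low values, over a range of 0.00103 to 0.217). IER3, an early response gene, rose by 0.41 and NFKBIA, the inhibitor of NF-kappaB, rose by 0.20. Fatty acid synthesis genes had 4 of 12 higher and 1 lower, or 5 and 1 adjusted over the list alone (adjusted p = 0.027, and 0.152 with an estimated correlation). The call was lost without SETDB1 DMSO replicate 3 (0.0668, over a range of 0.000144 to 0.152). FADS1, a fatty acid desaturase, rose by 0.30.

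The remaining lists were not called in SETDB1 against NC at the preset correlation. With fry, p53 targets passed as lower (adjusted p = 0.00015). NRF2 targets (7.75e-05), lysosome genes (0.00275) and the methylation machinery (2.3e-05) passed as higher with fry. Hypoxia response genes had 9 of 18 higher and 4 lower (adjusted p = 0.116). This list passed without NC replicate 1 (0.0309), with chromosome neighbours subtracted (0.0157) and with fry, over a range of 0.00446 to 0.428. STC2, a secreted glycoprotein, rose by 0.61 and BHLHE40 fell by 0.63. Counts of genes higher and lower were 5 and 1 of 52 for oxidative phosphorylation (adjusted p = 0.291, and 0.0413 without SETDB1 DMSO replicate 3, over a range of 0.0413 to 0.823) and 4 and 3 of 17 for the tricarboxylic acid cycle. They were 5 and 7 of 38 for p53 targets, where PLK2, a kinase, fell by 0.90 and CDKN1A, an inhibitor of cyclin-dependent kinases, fell by 0.42. These 4 lists had the same counts adjusted over the list alone. The counts were 5 and 6 of 28 for epithelial junction genes (5 and 7 adjusted over the list alone), with ELF3 higher by 0.49. S phase genes had 3 and 1 of 32 (1 and 1 adjusted over the list alone), with a median of -0.009 and a mean of 0.011. Nuclear transport genes had 3 and 9 of 36 (4 and 10 adjusted over the list alone), and XPO1 itself was at 80.8 ± 4.38 and 81 ± 2.45 FPKM (adjusted p = 0.968). The methylation machinery for H3K9 and DNA, of which SETDB1 is a member, had 4 and 0 of 25 (3 and 0 adjusted over the list alone).

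Integrated stress response genes had 3 and 3 of 22 higher and lower, heat shock genes 2 and 3 of 18, lysosome genes 4 and 4 of 30 and protocadherins 1 and 4 of 20, with the same counts adjusted over the list alone. GLA, a lysosomal galactosidase, rose by 0.90. The protocadherins had a median of 0.055 and a mean of -0.004. Adjusted over the list alone, counts differed for endoplasmic reticulum chaperones (3 and 5 of 20, then 4 and 9), cholesterol synthesis (3 and 4 of 24, then 4 and 5) and NRF2 targets (7 and 3 of 19, then 8 and 4). They also differed for immediate early genes (6 and 9 of 28, then 7 and 9), numbered zinc finger genes (37 and 16 of 393, then 26 and 10) and replication-dependent histones (3 and 2 of 46, then 2 and 2). AKR1C3, an aldo-keto reductase, rose by 0.87, and FDFT1, which makes squalene, rose by 0.53. Histones passed as a list only with chromosome neighbours subtracted (0.0206, over a range of 0.0206 to 0.977). Of the markers of other cell types, fibroblast genes had 1 and 1 of 4 (2 and 2 adjusted over the list alone), with a median of 0.004 and a mean of -0.06, and passed at a mean FPKM of at least 5 (0.0357, over a range of 0.0357 to 0.984). Blood genes had 0 and 0 of 3 (0 and 1 adjusted over the list alone), and endothelial genes had 0 and 0 of 2 in both counts.

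In all, limma called 1643 genes higher and 1475 lower in SETDB1 against NC out of 11505, and the median absolute log2 fold change of the called genes was 0.27. Groups did not overlap for 40.6% of genes, where chance gives 10%. Called genes lay next to each other on the chromosomes more often than in 10000 random placements. Adjacent pairs within 100 kb that were both higher numbered 392 against a mean of 173.1, and pairs both lower 270 against 139.4 (permutation p = 0.0001 for each, the smallest the placements can give). On chromosome 16 from 28950937 to 30400108, 29 of 40 tested genes were higher and 0 lower (median 0.46), and on chromosome 3 from 49724294 to 52239158, 26 of 40 were higher and 2 lower (median 0.32). Consecutive windows on chromosome 9 from 121201483 to 133348131 had 23, 23 and 24 of 40 higher and 0, 1 and 1 lower. Other windows were lowered, with 23 of 40 lower and 0 higher on chromosome 15 from 79311112 to 88913379 (median -0.207). On chromosome 20 from 270863 to 4701588, 22 of 40 were lower and 1 higher (median -0.2). With the change of chromosome neighbours subtracted, 1235 genes were higher and 1161 lower, and 1979 of the 3118 calls were kept.

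**Figure D2:**
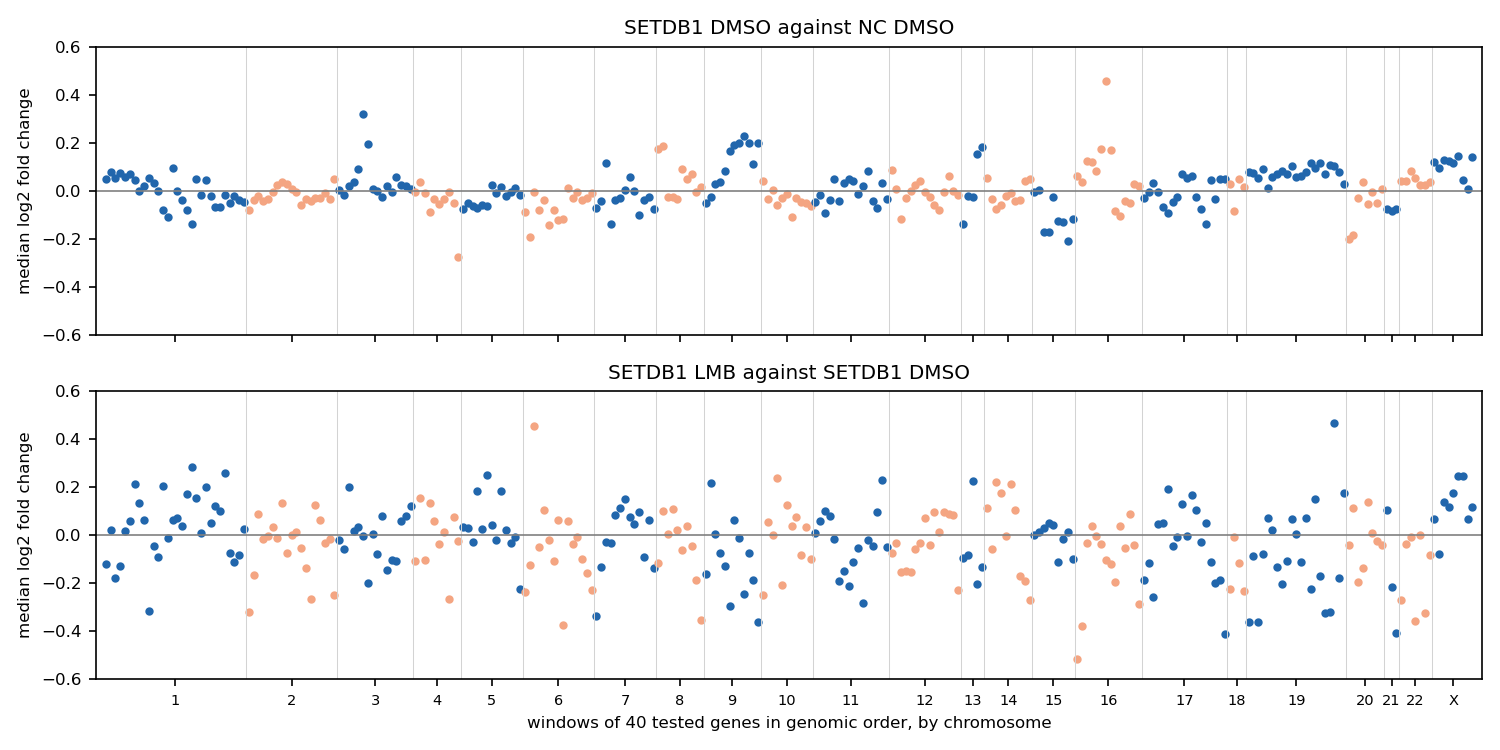
Median log2 fold change of windows of 40 tested genes in genomic order, coloured by alternating chromosome, for SETDB1 DMSO against NC DMSO (top) and SETDB1 LMB against SETDB1 DMSO (bottom). The highest window in the top panel is that on chromosome 16 at 0.46, and the SD of the window medians was 0.084 at the top, against 0.03 for shuffled genes, and 0.152 at the bottom, against 0.122 for shuffled genes (highest of 1000 shuffles 0.139).

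The next comparison asked what LMB changed in SETDB1 cells. Genes of DNA replication and mitosis fell, and most p53 targets and most interferon response genes rose. As a list, the mitosis genes were not called with an estimated correlation (camera adjusted p = 0.0593). XPO1, the receptor that LMB blocks, went from 81 ± 2.45 to 138 ± 6.86 FPKM (SD, n = 3; log2 fold change 0.76, SE 0.0521, adjusted p = 9.32e-09). SETDB1 itself was at 409.6 ± 14.7 and 417 ± 11.9 (log2 fold change 0.03, adjusted p = 0.586). MYC fell from 47.1 ± 2.56 to 26.8 ± 0.771 (-0.79, SE 0.0485, adjusted p = 3.06e-09). LDHA rose from 317 ± 11.2 to 363 ± 3.17 (0.20, SE 0.0482, adjusted p = 0.00188). The share of MTRNR2L genes, given above, rose with LMB beside each of these changes.

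All 32 S phase genes fell, also adjusted over the list alone, with a median of -2.0 and an adjusted p of 1.21e-13, or 0.00454 with an estimated correlation. CDC45, part of the replicative helicase, went from 19.1 ± 1.42 to 0.5 ± 0.144 FPKM (-3.75). GINS2, another helicase subunit (-3.40), and MCM3 (-2.50) and MCM7 (-2.41), of the helicase core, also fell. All 32 mitosis genes fell, also adjusted over the list alone, with a median of -2.25 (adjusted p = 1.02e-14, and 0.0593 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, went from 47.7 ± 1.13 to 4.59 ± 0.333 (-3.13). TOP2A, a topoisomerase (-2.81), BUB1, a checkpoint kinase (-2.75), and PRC1, a spindle midzone protein (-2.66), fell with it. LMNB1 (lamin B1), with 74.2 ± 1.45 and 5.05 ± 0.234 FPKM (-3.63), MYBL2 (-3.42), CENPM (-3.39) and PRIM1, a primase subunit (-3.19), were also among the largest falls.

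Of 38 p53 targets, 33 rose and 3 fell, also adjusted over the list alone, with a median of 1.27 (adjusted p = 4.08e-10, and 0.00549 with an estimated correlation). CDKN1A went from 78 ± 2.33 to 408 ± 16.5 FPKM (2.37, adjusted p = 6.87e-14). TNFRSF10B, a death receptor, rose by 2.21, TP53INP1 by 2.66 and BTG2, an antiproliferative gene, by 1.72. GADD45A, a growth arrest gene outside the list, was among the largest rises, from 6.96 ± 0.666 to 74.2 ± 4.18 (3.24). Of 31 interferon response genes, 28 rose and 0 fell, also adjusted over the list alone, with a median of 0.81 (adjusted p = 7.84e-08, and 0.00917 with an estimated correlation). PARP9 rose by 1.56, IFIH1, a sensor of double-stranded RNA, by 1.65, STAT2 by 1.31 and DTX3L by 1.41.

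The glycolysis and lactate list was not called, with 8 of 24 genes higher and 16 lower, also adjusted over the list alone, and a median of -0.27 (adjusted p = 0.184). ALDOC, an aldolase, went from 9.72 ± 0.206 to 47.9 ± 2.02 FPKM (2.19). HK2 went from 12.5 ± 0.339 to 3.27 ± 0.189 (-1.66), PDK1, a kinase that inhibits pyruvate dehydrogenase, fell by 1.42, and ENO2 fell by 1.13. Of 50 MYC targets, 8 rose and 35 fell, also adjusted over the list alone, with a median of -0.43 (adjusted p = 0.000712, and 0.158 with an estimated correlation). FBL, the nucleolar methyltransferase fibrillarin, went from 180.1 ± 9.27 to 70.1 ± 4.03 (-1.35). UNG, a DNA glycosylase (-1.16), TCOF1, a nucleolar protein (-1.32), and TMEM97, a sterol-binding membrane protein (-1.45), fell as well.

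Estrogen receptor targets fell, with 4 of 30 higher and 26 lower, also adjusted over the list alone, and a median of -0.56 (adjusted p = 0.000232, and 0.0423 with an estimated correlation). ESR1, the receptor itself, went from 69.6 ± 2.69 to 17 ± 0.875 FPKM (-1.97). XBP1 went from 1297 ± 26.9 to 315 ± 8.09 (-2.04), MYB fell by 1.86, and AREG fell by 1.46. Luminal identity genes had 2 of 17 higher and 14 lower, also adjusted over the list alone (adjusted p = 0.00347, and 0.257 with an estimated correlation), and besides ESR1 and XBP1, AR (-1.32) and GATA3, a luminal transcription factor (-0.83), fell. AGR3, a disulfide isomerase (-3.44), and CALML5, a calmodulin-like protein (-3.35), were among the largest falls.

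Mesenchymal and invasion genes had 13 of 20 higher and 5 lower, also adjusted over the list alone, with a median of 0.47 (adjusted p = 0.027, and 0.14 with an estimated correlation). The call was also lost at a mean FPKM of at least 5 (0.538), over a range of 1.6e-07 to 0.538. At that filter the mean log2 fold change of the list was 0.171 in place of 0.569, so the more abundant members rose less. SNAI1, a repressor of E-cadherin, went from 0.6 ± 0.351 to 11.4 ± 1.19 FPKM (2.97) and FN1 from 7.64 ± 0.325 to 22.6 ± 1.09 (1.45). CCN2, a matricellular protein, rose by 2.13 and PLAU, the urokinase protease, by 1.31. The largest rise was that of ACTG2, a smooth muscle actin, from 2.27 ± 0.153 to 84 ± 0.955 (4.70). The keratins KRT17, KRT16 and KRT13 rose by 4.40, 3.45 and 3.31. SERPINI1, a serine protease inhibitor, rose by 3.90, CGA, the common subunit of glycoprotein hormones, by 3.60 and RAB37, a vesicle GTPase, by 3.45.

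Lysosome genes had 21 of 30 higher and 6 lower (adjusted p = 0.00561, and 0.0831 with an estimated correlation), with CTSL, a cathepsin, higher by 1.05, PSAP, the prosaposin gene, higher by 0.85 and GLA lower (-1.34). NRF2 targets had 2 of 19 higher and 15 lower (adjusted p = 0.00143, and 0.0593 with an estimated correlation). NQO1, a quinone reductase, went from 358 ± 11.1 to 122 ± 0.964 FPKM (-1.54), and TKT, transketolase, fell by 1.93. Fatty acid synthesis genes had 0 of 12 higher and 10 lower (adjusted p = 0.00416, and 0.0836 with an estimated correlation), with lower FADS1 (-1.62) and ELOVL5, a fatty acid elongase (-1.58). Integrated stress response genes had 4 of 22 higher and 15 lower (adjusted p = 0.0103, and 0.0937 with an estimated correlation). In that list the alanyl-tRNA synthetase AARS1 fell by 1.78 and the transcription factor ATF3 rose by 3.01. Nuclear transport genes had 8 of 36 higher and 26 lower (adjusted p = 0.011, and 0.396 with an estimated correlation). NXF1, the mRNA export receptor, went from 22.6 ± 0.525 to 80.1 ± 1.57 FPKM (1.78), while RCC1, the exchange factor of RAN (-1.77), and the importin KPNA2 (-1.32) fell. These 5 lists had the same counts adjusted over the list alone.

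Cytosolic ribosomal protein genes had 11 of 84 higher and 51 lower, or 11 and 50 adjusted over the list alone (adjusted p = 0.0267, and 0.803 with an estimated correlation). That call was lost without SETDB1 DMSO replicate 2 (0.088), without LMB replicate 1 (0.078) and with quantile normalization (0.197), over a range of 0.00307 to 0.803. RPL3 went from 1076 ± 44.8 to 545 ± 21.2 FPKM (-0.98), and RPS27L, a paralog that is also a p53 target, rose by 1.31. Numbered zinc finger genes, many of them repressors that recruit SETDB1 through TRIM28, had 207 of 393 higher and 88 lower, or 207 and 85 adjusted over the list alone (adjusted p = 0.00176, and 0.396 with an estimated correlation). ZNF117 rose by 1.61 and ZNF367 fell by 1.90. Histone genes had 27 of 46 higher and 9 lower, also adjusted over the list alone (adjusted p = 0.0334, and 0.417 with an estimated correlation). The call was lost without LMB replicate 3 (0.0617) and with quantile normalization (0.0567), over a range of 0.000763 to 0.417. The mean log2 fold change of the list was 0.3, with 0.26 without LMB replicate 3 and 0.394 with quantile normalization. H2BC4 rose by 1.87 and H3C8 fell by 1.68. Of the markers of other cell types, fibroblast genes had 4 of 4 higher, also adjusted over the list alone (adjusted p = 0.021, 0.332 with an estimated correlation, and 0.065 at a mean FPKM of at least 5, over a range of 5.65e-07 to 0.332). The mean log2 fold change of these fibroblast genes was 1.229, and 1.885 at a mean FPKM of at least 5. The highest of them was ACTA2, another smooth muscle actin, from 2.78 ± 0.213 to 29 ± 2.11 (2.99), while COL1A1 was at 3.02 ± 0.278 with LMB. Basal markers had 5 of 8 higher and 1 lower (adjusted p = 0.149), blood markers 3 of 3 higher (0.149) and endothelial markers 0 of 2 (0.952, median -0.012 and test direction up), with the same counts adjusted over the list alone. Basal (adjusted p = 6.3e-07) and blood markers (1.1e-05) passed as higher with fry.

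Lists not called in LMB against DMSO included oxidative phosphorylation, with 20 of 52 higher and 16 lower, a median of 0.034 and a mean of -0.021, and the tricarboxylic acid cycle, with 7 of 17 higher and 5 lower, a median of 0.00 and a mean of -0.12. In them NDUFS2, of respiratory complex I (-0.84), and CS, citrate synthase (-0.98), fell. Hypoxia response genes had 10 of 18 higher and 6 lower (10 and 7 adjusted over the list alone), and epithelial junction genes had 11 of 28 higher and 13 lower (11 and 14 adjusted over the list alone). NDRG1 rose by 0.96, while CLDN7, a claudin, fell by 0.87. The methylation machinery had 8 of 25 higher and 15 lower. UHRF1 (-2.79) and DNMT1 (-2.04), which maintain DNA methylation, and CBX5, a heterochromatin protein (-1.81), fell. Genes higher and lower numbered 10 and 6 of 18 for heat shock, where HSPA4L rose by 1.67, and 7 and 15 of 24 for cholesterol synthesis, where MVK, mevalonate kinase, fell by 1.49. They numbered 5 and 2 of 8 for NF-kappaB genes, 10 and 4 of 20 for endoplasmic reticulum chaperones and 16 and 10 of 28 for immediate early genes, where FOSL1 rose by 2.67. Protocadherins had 9 and 7 of 20. Apart from hypoxia response and epithelial junction, these lists had the same counts adjusted over the list alone. Fry called all lists of this paragraph except oxidative phosphorylation (adjusted p = 0.94), endoplasmic reticulum chaperones (0.203) and protocadherins (0.187).

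**Figure D3:**
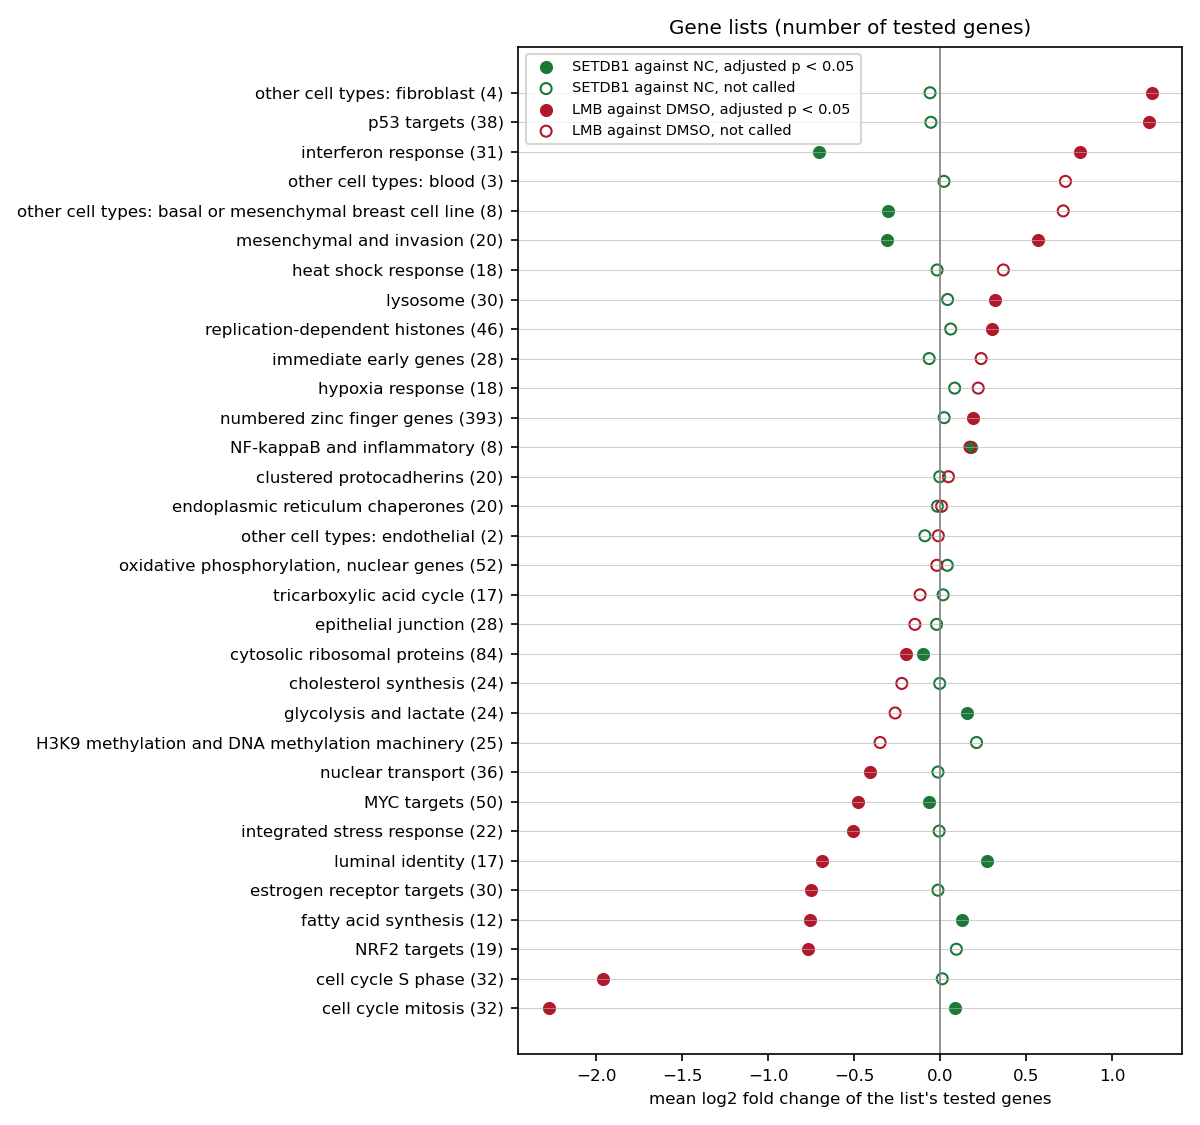
Mean log2 fold change of the tested genes of each list (number of genes in brackets) for SETDB1 against NC (green) and LMB against DMSO (red), filled where the camera adjusted p at the preset correlation was under 0.05. Interferon response genes stood at -0.71 in the first comparison and 0.81 in the second, and the cell cycle lists at -1.96 and -2.28 in the second.

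In LMB against DMSO, limma called 4389 genes higher and 4893 lower out of 11505, and the median absolute log2 fold change of called genes was 0.53. Groups did not overlap for 82.7% of genes, where chance gives 10%, and 13 of the 17 list calls were lost with an estimated correlation.

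SETDB1 cells with LMB were also set against NC cells with DMSO, which differ in both genotype and treatment. SETDB1 was higher by 3.96 (SE 0.0454, adjusted p = 6.91e-16), XPO1 by 0.77 (adjusted p = 8.86e-09) and LDHA by 0.17 (adjusted p = 0.00623), and MYC fell by 0.82 (adjusted p = 2.02e-09). ACTG2 rose by 6.05, KRT17 by 4.39 and SERPINI1 by 3.98, and CGA, RAB37 and KRT13 rose by 3.89, 3.85 and 3.75. TSPYL2 went from 6.43 to 73.3 FPKM (3.32). LMNB1 (-3.64), CDC45 (-3.59), GINS2 (-3.50), AREG (-3.32), CENPM (-3.25), PRIM1 (-3.17) and MYBL2 (-3.14) fell, and TUBB, a beta-tubulin, went from 451 to 48.1 FPKM (-3.20).

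S phase genes (0 of 32 higher and 32 lower, adjusted p = 1.21e-13) and p53 targets (33 of 38 higher and 4 lower, adjusted p = 1.83e-09) were also called with an estimated correlation (0.00454 and 0.00549). The interferon list was not called, with 15 of 31 higher and 13 lower and a median of 0.11 (adjusted p = 0.557). In it IFI27 rose by 1.83 and STAT2 by 1.30. The glycolysis list had 10 of 24 higher and 12 lower (adjusted p = 0.692), with ALDOC higher by 2.24. MYC targets had 5 of 50 higher and 39 lower (adjusted p = 5.07e-05, and 0.107 with an estimated correlation), with UNG lower (-1.38). Mesenchymal and invasion genes had 13 of 20 higher and 7 lower (adjusted p = 0.193), and basal markers had 3 of 8 higher and 5 lower, with a median of -0.27 and a mean of 0.41. These lists had the same counts adjusted over the list alone. With fry, the interferon (adjusted p = 9.68e-06), mesenchymal and invasion (3.73e-05) and basal lists (1.08e-05) passed as higher. Endoplasmic reticulum chaperones had a median of 0.13 and a mean of -0.01. In all, 4441 genes were higher and 4897 lower, 80.8% of genes did not overlap between the groups where chance gives 10%, and 13 of 15 list calls were lost with an estimated correlation.

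Genes that moved one way with SETDB1 and the other way with LMB numbered 1538 of the 3118 called in SETDB1 against NC, and 1070 moved the same way in both. Independent lists would give 1261 and 1254. Of the 1538, 901 were higher with SETDB1 and lower with LMB (699 for independent lists), and 637 were lower and then higher (563 for independent lists). Both comparisons use the SETDB1 DMSO libraries with opposite sign, so part of the excess may come from these shared libraries, which cannot be split into parts of 2. Across genes, Pearson's r of the fold changes was -0.14, and in unchanged groups simulated 50 times it was -0.498. The simulated r follows from the shared libraries alone, while the observed r also depends on the larger changes with LMB. The r values therefore do not tell which has more opposite change. The simulations called a mean of 0 genes in opposite directions and 0 in the same direction. No gene was changed in them, so almost no calls of any kind could arise. That 0 therefore does not show how many opposite calls the shared libraries give when LMB changes most genes. The covariance was -0.0231 against -0.00314 in the simulations, a difference of -0.02. Of the 1538 genes, 413 were not called in SETDB1 with LMB against NC, 115 were still on the SETDB1 side of NC and 1010 were past it. SHH, which fell by 1.39 with LMB, remained above NC by 2.21, and MX1, which rose by 1.25, remained below NC (-0.55). MUC1 fell by 1.22 with LMB, and DHRS2 fell by 2.02.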

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

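The rescaling without MTRNR2L genes and the subtraction of chromosome neighbours were chosen after the results were seen, and all other alternatives were set before. No call of a gene list or of a gene named by the rule changed direction under any alternative. KRT8, named after its values were seen, was called higher in LMB against DMSO (0.18) and in LMB against NC (0.21) and lower in both with quantile normalization (-0.54). It was called higher in both with TPM (0.18 and 0.23) and with median-of-ratios scaling (0.18 and 0.21). Quantile normalization sets values by rank, so for the most abundant genes it shows a change of rank and not of level. Of 391 called results of named genes, 365 stayed past the threshold with the same sign under every alternative and 26 fell under it in at least 1, all in SETDB1 against NC. Most of these genes were picked for large changes or small p in these same data, so their stability does not extend to all calls. Without 1 library at a time, 2193 to 3038 of all 3118 calls in SETDB1 against NC were kept with the same sign. In LMB against DMSO, 8855 to 9273 of 9282 were kept. Requiring an absolute log2 fold change of at least 1 left 25 genes higher and 32 lower in SETDB1 against NC, 550 and 1057 in LMB against DMSO, and 592 and 1077 in LMB against NC, since most called changes were smaller than that. Of 42 calls of gene lists, 7 remained with an estimated correlation and fry, which asks only whether members move one way, called 70. Some calls were lost although the estimated correlation lay below the preset 0.01. Examples are mesenchymal and invasion genes in SETDB1 against NC (-0.00428) and NRF2 targets in LMB against DMSO (-0.0358). With an estimated correlation camera also uses fewer degrees of freedom, so such losses do not by themselves show correlated members. With the estimated correlation the glycolysis list in SETDB1 against NC (mean 0.153) had an adjusted p of 0.156, and the MYC targets had 0.332 (mean -0.065), 0.158 (mean -0.478) and 0.107 (mean -0.543) in SETDB1 against NC, LMB against DMSO and LMB against NC. With fry the glycolysis list passed in LMB against DMSO (mean -0.263, adjusted p = 4.06e-06) and in LMB against NC (mean -0.11, adjusted p = 4e-04).

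Without 1 library at a time, genes higher and lower numbered 1198 to 1871 and 1049 to 1718 in SETDB1 against NC, 4215 to 4455 and 4696 to 4976 in LMB against DMSO, and 4257 to 4422 and 4728 to 4873 in LMB against NC. The same settings gave 41 to 42 list calls and 1091 to 1814 opposite changes. The numbers of the replicates did not pair the libraries: r of their deviations from group means was -0.272 to 0.353 for equal numbers and -0.447 to 0.369 for different ones, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block, 1567 genes were higher and 1403 lower in SETDB1 against NC, 4371 and 4865 in LMB against DMSO, and 4419 and 4899 in LMB against NC. The share of higher genes among those called in SETDB1 against NC was 52.7%, and over the alternatives it lay between 50.4% and 59.1%. In LMB against DMSO it was 47.3%, between 46.9% and 53%. The lower estimated depth of SETDB1 DMSO replicate 1 limits low genes most, since a single read was worth an estimated 1.41 times as much there as in the NC libraries.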

Other observations

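The tests on serum response factor targets, on the MTRNR2L genes, on SETDB1 DMSO replicate 1, on the interferon list in LMB against NC, on the spread of chromosome windows and on other splits of the libraries were chosen or judged only after the results were seen, as were the families of tubulins, keratins and S100A genes and the place of the S100A genes. The tests on interferon genes of at least 10 FPKM, on adjacent gene pairs, on genes 20 apart and on GC content had their outcomes set before those values were computed. The test on genes 20 apart was added once the adjacent pairs had been counted, and that on GC content, with its cut, once the uncorrected rho of 0.15 was known.

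Several cytoskeletal families moved within themselves in different directions with LMB. Of 10 alpha and beta tubulin genes, which encode the subunits of microtubules, 7 fell and 2 rose against DMSO (also 7 and 2 among these 10 under each scaling). TUBB went from 409 to 48.1 FPKM, TUBA1B from 981 to 131 and TUBB4B from 459 to 131, all against a rise of TUBA4A from 1.97 to 5.38. Of 14 keratin genes, 7 rose and 3 fell (7 to 8 and 3 to 4 over the scalings). KRT13 and KRT17 rose, KRT15 went from 5.57 to 13.6 and KRT19 from 1557 to 973. KRT8 went from 5892 to 6688, and its log2 fold change of 0.18 was the same with TPM and median-of-ratios scaling. It turned to -0.54 only with quantile normalization, which sets values by rank. Among actins, the smooth muscle genes ACTG2 and ACTA2 rose while the cytoplasmic ACTB went from 1568 to 1192 and ACTG1 from 1547 to 918, and the log2 fold change of ACTB lay between -0.40 and -0.24 over the scalings.

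S100A genes, which encode small calcium-binding proteins, had 8 of 11 lower and 1 higher in SETDB1 against NC (7 to 8 of these 11 lower over the scalings), and 6 higher and 3 lower with LMB (2 lower with quantile normalization). S100A6 was the member that rose with SETDB1, from 48.4 to 96.4 FPKM. S100A10 went from 573 in NC to 408 in SETDB1 DMSO and 908 with LMB, and S100A11 from 1292 to 994 and 2103. S100A8 stayed low with LMB, at 0.36. All 11 lie on chromosome 1, and 9 of them share a window of 40 tested genes. Of the other 31 genes of that window, 11 were lower and 2 higher in SETDB1 against NC (median log2 fold change -0.112) and 22 were higher and 7 lower with LMB (median 0.298). With chromosome neighbours subtracted, 7 S100A genes were lower and 1 higher in SETDB1 against NC, and S100A1 lost its call (-0.48 before and -0.44 after, adjusted p = 0.0685). These families were tested gene by gene and not as lists.

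A candidate explanation for the rise of ACTG2 and ACTA2 is activation of serum response factor, whose targets include smooth muscle actins. A list of its targets without those genes had 19 of 30 tested members higher and 7 lower with LMB, and their mean log2 fold change was 0.48 (SD 0.87). The camera p was 0.00285 at the preset correlation and 0.0626 with an estimated one, so the hypothesis stays open. ACTB and ACTG1, both members of the list, fell.

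Interferon response genes were lower in SETDB1 DMSO and higher again with LMB, with list means of 4.02 to 4.05 per library in NC, 3.31 to 3.34 in SETDB1 DMSO and 4.13 to 4.15 with LMB on the log2 scale. The shallower library, SETDB1 DMSO replicate 1, was not the source, since the mean log2 fold change was -0.71 without it. Low genes near the floor were not the source either, since 16 members with a mean FPKM of at least 10 had a mean of -0.58 (SD 0.34). A difference between the NC and SETDB1 cultures other than SETDB1 itself cannot be told apart from an effect of SETDB1, because each genotype may come from a single derived culture, and the mean of 0.1 in LMB against NC does not separate them. Since no NC culture with LMB was analysed here, it also stays open whether the later rise depends on SETDB1.

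Genes that differed between SETDB1 and NC lay in shared chromosome segments. Pairs of neighbours both called lower were 1.94 times as frequent as in random placement (permutation p = 0.0001). The ratio for LMB against DMSO was 1.07 with the same permutation p, and since many more genes were called there, the ratios do not rank the comparisons. The reach was far longer than clusters of related genes: log2 fold changes of genes 20 apart correlated across genes at a Spearman's rho of 0.15 in SETDB1 against NC (highest of 1000 shuffles 0.025) and 0.002 in LMB against DMSO. In LMB against NC, which holds the same difference between cultures, the rho was also only 0.007 (highest of 1000 shuffles 0.032). The larger changes with LMB can hide such segments, so the rho of 0.002 does not show that they are absent from LMB against DMSO. LMB against DMSO was not free of local grouping, since the SD of its window medians was 0.152 against 0.122 for shuffled genes (highest of 1000 shuffles 0.139). In SETDB1 against NC, a smooth trend on GC content and transcript length, once removed, left a rho of 0.139. A copy number difference between the NC and SETDB1 cultures, which MCF7 sublines could carry, gives this pattern and is one hypothesis for part of the smaller changes, such as ALDOA on chromosome 16. SETDB1 acting over whole chromosome domains cannot be told apart from it, since the SD of window medians (0.084, against 0.03 for shuffled genes) needs a culture of independent origin to be read.

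MTRNR2L genes took 7.25% of summed FPKM with LMB and 2.82% without. The sum rose under each of 4 scalings, with a lowest ratio of 1.55 and a highest of 2.58, so scaling did not account for the whole rise. MTRNR2L2 rose by 1.47 on the log2 scale as deposited, with TPM and with median-of-ratios scaling, and by 0.13 with quantile normalization. Quantile normalization gives genes of equal rank the same value in every library, which limits the rise of the most abundant genes. With it, MTRNR2L2 had a log2 fold change of 0 in SETDB1 against NC. The smaller rise there therefore does not tell whether scaling between libraries accounts for part of the rise. The 8 members, on 8 chromosomes, rose by ratios of 2.02 to 3.46, but with quantile normalization only 7 were called higher and MTRNR2L2 was not (log2 fold change 0.13, adjusted p = 0.278). The SD of their log2 ratios, 0.26, lay below the 5th percentile of random sets matched on level (0.31, median 0.6). This is consistent with reads from a single shared source, which may be mitochondrial ribosomal RNA, rather than 8 separate genes. Whether LMB raised that RNA or changed how much of it entered the libraries stays open.

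In each comparison, 10 splits of the 6 libraries into 3 and 3 were fitted, and 1 of the 10, the real one, called as many genes. The real splits called 3118, 9282 and 9338 genes in SETDB1 against NC, LMB against DMSO and LMB against NC, and the highest of the other splits called 0 in each. With 10 splits a share under 0.05 cannot be reached. Every other split mixed libraries of both real groups, so the difference between them entered the spread within each group. Calls of 0 there thus do not measure how many genes chance would call.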
